A study of Mus musculus with 51 samples.

How the data were processed

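Total RNA, extracted with Trizol and labelled with biotin per the labels' protocols, of sorted lacZ-positive cells and of unsorted tissue was hybridized to 51 Affymetrix mouse whole genome arrays, 1 sample each. The deposited values are probe set intensities on a linear scale, 1 column per array. How the authors summarized and scaled them is not given in the sources used here. Array medians lie close together but the distributions are not identical. The table holds 45101 probe sets, of which 64 are controls. Detection calls were not used here.

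A single probe set with 2 values far above all others was left out; the highest other intensity was 21364. Intensities below 32 were set to 32 (37.4% of values) and log2 was taken, so a value of 5 is the floor. This floor is a fixed setting and no measure of background on these arrays. The deposited scaling was kept. A gene symbol came from the platform annotation, updated through Entrez identifiers with the RefSeq table of GRCm38.p6, which matched 34753 probe sets. Of all probe sets 34944 had 1 symbol, 932 had several and 9160 had no listed gene, and only the first were tested. A genome build for the values is not given in the sources used here and no coordinates are printed. Each gene was represented by the probe set with the highest mean over all arrays, and it was tested if above the 40th percentile of its array on at least 4 arrays, which left 15150 of 18192 genes.

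Groups came from the sample labels. Comparisons were sorted primary tumor minus sorted hyperplasia, unsorted primary tumor minus wild-type gland, sorted minus unsorted primary tumor, transplanted minus primary tumor within sorted and within unsorted samples, and the difference between these last ones. All 6 groups were fitted together with lmFit and eBayes in limma 3.58.1 (R 4.3.3) on 50 replicates, with mouse of origin as a random block (duplicateCorrelation, consensus correlation 0.358). The block weights mice, so a fitted difference can depart from the difference of group means. P-values were adjusted by Benjamini-Hochberg and called under 0.05. A fold against a group at the floor on every array is a lower bound, the brighter group's mean over the floor.

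There were 22 gene lists: AP-1 subunits, immediate early and dissociation response, AP-1 associated invasion, RAS-MAPK feedback, luminal, milk and alveolar, hormone-sensing luminal, luminal progenitor, basal and myoepithelial, cell cycle, adipocyte, endothelial, fibroblast and matrix, T and NK cell, B and plasma cell, macrophage and myeloid, skeletal muscle, erythroid, interferon response, mesenchymal transition, hypoxia and glycolysis, and MHC class II. Groups, lists, tests, alternatives and the naming rule were set before the data were examined, apart from alternatives stated as added. Lists were tested with cameraPR at an inter-gene correlation of 0.01 and again with the estimated correlation, adjusted over the 22 lists of a comparison, and with fry. Over the 6 comparisons 40 list shifts were called, and 6 of these with the estimated correlation: AP-1, immediate early, endothelial and hormone-sensing in tumor against gland, and AP-1 and immediate early in the sort.

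Named genes were the 8 largest rises and falls for progression and tumor against gland, 5 for the others and 3 for the difference of transplant effects, among genes past the threshold whose higher group's mean lay above the median of all probe sets. Transcripts without an established name were skipped. A fixed set of 16 genes was added whatever the result, as were up to 3 called members of each described list. Overlaps used Fisher's exact test. Control probe set ratios were compared by exact permutation tests, two-sided, adjusted over 15 tests. Permutations and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

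The fit was tested on simulated values for 15150 genes, with 100 genes changed at each size, drawn from genes whose mean lay above the median gene. For the progression comparison 53% of 2-fold and 88% of 4-fold changes were recovered, for tumor against gland 68% and 98%, for the sort 86% and 100%, for sorted transplants 82% and 97% and for unsorted transplants 63% and 95%. With no change simulated, no gene was called in any comparison, and 1 list was called, in the difference of transplant effects. With changes planted, 7 to 9 unchanged genes were called in each of the comparisons above. The simulated spread was independent between genes, whereas the interferon list had an estimated inter-gene correlation of 0.787. Each gene also had the same simulated spread in every group, which was not so in the data. The simulation therefore does not show how often correlated genes or lists are called without a change, nor how often changes of dim genes are recovered. Nor does it show how the fit performs where the groups compared differ in spread. In alternative settings, genes with no residual spread, mostly those at the floor on every array, were left out of the variance estimates and counted as not passing (2803 genes with the floor at 100). Alternatives covered normalization, floor, filter, probe set choice, block, samples in the fit, variance model, weights, covariates, thresholds and left-out arrays.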

Results

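Gene expression was measured on 51 Affymetrix mouse arrays from a model in which Wap-Cre switches on a conditional Etv6-NTRK3 allele in mammary epithelium. Etv6-NTRK3 joins the transcription factor gene Etv6 to the kinase part of NTRK3. A floxed lacZ reporter marked the recombined cells, so that lacZ-positive cells could be sorted. The arrays fall into 6 groups. Sorted cells came from hyperplastic glands (4 arrays, 4 mice), primary tumors (8 arrays, 6 mice) and transplanted tumors (7 arrays, 5 mice of origin, passages 1 to 4). Unsorted tissue came from primary tumors (23 arrays of 22 tumors, 14 mice), transplanted tumors (4 arrays, 2 mice of origin) and wild-type mammary glands (5 arrays, 5 mice). Transplants grew in RAG2-deficient hosts, which lack mature B and T cells. The median intensity of an array lay between 42.9 and 57.8, and the number of arrays limits the precision. The 2 arrays of 1 unsorted tumor correlated at r = 0.987 across genes and were averaged into 1 replicate. Values below are log2 differences ± SE from limma or group means ± SD. Each SE and limma p rests on a spread per gene pooled over all 6 groups. It can therefore understate the spread in the groups compared.

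The first question was what separated sorted tumor cells from sorted hyperplastic cells of the same model. Tumor cells had higher levels of Prtn3, a serine protease of granulocytes (9.30 ± 1.06, SD, n = 8, against 6.05 ± 0.98, n = 4; difference 3.18 ± 0.53, limma adjusted p = 9.55e-05). Car12, a carbonic anhydrase, rose by 3.00 ± 0.61, and Col9a3, a collagen chain of cartilage, rose by 2.83 ± 0.57. The ubiquitin ligase gene Rnf128 rose by 2.74 ± 0.44, the growth factor gene Igf2 by 2.44 ± 0.69, the glutathione peroxidase gene Gpx2 by 2.47 ± 0.70, Mia by 2.37 ± 0.55 and Phlda3 by 2.34 ± 0.40. Of the 8 largest falls 6 were of immunoglobulin genes or Jchain, which antibody-producing cells express. Jchain, the joining chain of IgA and IgM, had a difference of -4.74 ± 0.81, Igkv8-30 of -3.99 ± 0.85, Igkv6-14 of -3.82 ± 0.49, Igk of -3.64 ± 0.52, Iglv1 of -3.34 ± 0.54 and Igha of -3.31 ± 0.36. Retnla, a product of alternatively activated macrophages and fat tissue, had a difference of -4.59 ± 1.18, and the fatty acid carrier gene Fabp4 of -3.24 ± 0.95. Where only some arrays of the lower group lay above the floor of 5, a difference is limited by the floor. In hyperplasia this was so for Car12 (2 of 4 arrays above it), Prtn3, Gpx2 and Mia (3 of 4 each), and in tumor cells for Igk and Igkv6-14 (1 of 8 each), Iglv1 (3 of 8), Jchain (5 of 8) and Retnla (7 of 8). In all, 573 of 15150 genes passed at adjusted p under 0.05, 195 higher and 378 lower in tumor cells. Gpx2 lost its call without any 1 of the 4 hyperplasia replicates (adjusted p from 0.0519 to 0.129), Igf2 without replicate 1 or 2 (0.195 and 0.0896), Retnla without replicate 1 or 2 (0.0805 and 0.0621), Fabp4 without replicate 1, 3 or 4 (0.187, 0.0911 and 0.0613) and Mia without replicate 1 (0.113). Without replicates 1 and 2 together, left out after seeing the data for their spike-in signal, Prtn3, Rnf128, Phlda3, Igkv6-14, Igk and Igha kept their calls and the other 10 of these 16 genes lost them.

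Among the gene lists, those of stromal and immune cells were lower on average in sorted tumor cells. Tumor and hyperplasia arrays overlapped in the mean of each of these 5 lists. Of 17 fibroblast and matrix genes 5 fell and none rose (9 fell when adjusted over the list alone), with a median difference of -1.51. Dpt (-3.20 ± 0.74), Lum (-2.92 ± 0.73) and Pdgfra (-2.38 ± 0.47) were among them. Of 11 B and plasma cell genes 6 fell (8 adjusted over the list alone, median -1.01), including Ighm (-2.82 ± 0.56) and Ms4a1 (-1.81 ± 0.45). Of 13 T and NK cell genes 5 fell (8 adjusted over the list alone, median -0.68). Cd28, a T cell costimulatory receptor, was at the floor in all 8 tumor arrays and at least 3.91-fold lower than in hyperplasia. Its SD was 1.48 in hyperplasia (n = 4) and 0 in tumors, while the pooled SE of the difference was 0.29. Of 13 endothelial genes 4 fell (6 adjusted over the list alone, median -0.85), among them Tek (-1.57 ± 0.28) and Plvap (-1.61 ± 0.43). Of 20 macrophage and myeloid genes 1 fell, Itgam (-1.13 ± 0.33), and 6 fell adjusted over the list alone (median -1.17). Ms4a1 was above the floor in 2 of 8 tumor arrays, Tek in 4 and Plvap in 7. The camera test called these 5 lists lower, at adjusted p from 5.38e-09 (fibroblast) to 0.000318 (macrophage). With an estimated correlation none was called, with adjusted p = 0.0587 for the T and NK and B and plasma lists, 0.25 for the fibroblast and endothelial lists and 0.558 for the macrophage list. Without hyperplasia replicates 1 and 2 together the T and NK, B and plasma and macrophage calls were lost (adjusted p = 0.0526, 0.217 and 0.123), as were those of Dpt, Lum, Ighm, Ms4a1, Cd28 and Itgam (from 0.0948 to 1). Single hyperplasia replicates ended the calls of Dpt and Lum (replicate 1, adjusted p = 0.0516 and 0.0538), Ms4a1 (1 or 2, 0.206 and 0.152), Plvap (3 or 4, 0.0527 and 0.0814) and Itgam (1, 2 or 4, 0.217, 0.167 and 0.0582).

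Among epithelial genes Wap, the milk protein gene whose promoter drives Cre, fell by 3.08 ± 0.77, while the casein gene Csn2 did not pass (-0.20 ± 0.45, adjusted p = 0.871). The milk list was called lower at adjusted p = 0.0463 with 1 of 14 members lower (2 adjusted over the list alone), and had adjusted p = 0.558 with an estimated correlation. Cited1, a hormone-sensing luminal gene, was at the floor in all 8 tumor arrays and at least 2.37-fold lower. The hormone-sensing list was called lower (1 of 9, 2 adjusted over the list alone, adjusted p = 0.0224, and 0.137 with an estimated correlation). Keratin genes did not pass: Krt8 0.04 ± 0.31, Krt18 -0.19 ± 0.34, Krt5 2.19 ± 1.07 and Krt14 1.80 ± 0.66. Of 13 basal genes Cdh3, above the floor in 3 of 4 hyperplasia arrays, rose (1.73 ± 0.47) and Myh11, above it in 4 of 8 tumor arrays, fell (-2.02 ± 0.54), and the list was not called. No AP-1 subunit gene of 8 passed, with Fos at -0.16 ± 0.49, Jun at -0.25 ± 0.29, Junb at -0.28 ± 0.31 and Fosl1 at 0.80 ± 0.43. The list of RAS-MAPK feedback genes was called higher with no member past the threshold over all genes and 3 adjusted over the list alone (median 0.43, adjusted p = 0.0117, and 0.287 with an estimated correlation). The hypoxia and glycolysis list was called higher with no member past the threshold (median 0.53, adjusted p = 0.0115, and 0.558 with an estimated correlation). The cell cycle list was called lower with no member past it (median -0.22, adjusted p = 0.0463, and 0.779 with an estimated correlation), and Mki67 did not pass (-0.82 ± 0.37). The MHC class II list was called lower (median -1.06, 1 of 6 adjusted over the list alone, adjusted p = 0.0127, and 0.558 with an estimated correlation). The cell cycle call was lost without hyperplasia replicate 1, 2 or 3 (adjusted p = 0.0963, 0.0652 and 0.0838), and the milk and hormone-sensing calls without replicate 3 (0.0838 and 0.0739) or 4 (0.293 and 0.0711). Wap lost its call without replicate 1 (0.0724), Cdh3 without 1 or 2 (0.155 and 0.0895) and Myh11 without 1, 3 or 4 (0.0539, 0.062 and 0.0658). With the spike-in signal as a covariate, added after seeing the data, the RAS-MAPK and hypoxia calls were lost (both 0.0563), as were the macrophage and MHC class II calls (both 0.487). Without hyperplasia replicates 1 and 2 together the RAS-MAPK, MHC class II and cell cycle calls were lost (0.0523, 0.123 and 0.29).

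The count of progression calls depended on the fit and on single arrays. Fitted with these 2 groups alone 13 genes passed: of the 8 largest rises and 8 largest falls, Igha alone passed. In the fit of all groups 157, 280 or 946 genes passed without hyperplasia replicate 1, 2 or 4. The bacterial spike-in transcripts BioB and BioC, added to each sample before hybridization, were brighter on hyperplasia replicates 1 (12.68) and 2 (11.38) than on the other hyperplasia arrays, 9.39 and 9.09. The group means were 10.63 ± 1.70 (SD, n = 4) and 9.10 ± 0.70 in tumors (n = 8, exact permutation p = 0.0424, 0.127 adjusted over 15 tests). Without both bright arrays 84 genes passed, 7 higher and 77 lower, and with the spike-in signal as a covariate 158, 36 higher and 122 lower. The Gapdh 3' over 5' ratio split the sorted arrays into those below and above -0.1, 3 and 1 in hyperplasia and 4 and 4 in primary tumors. Ratio and sample order cannot be told apart here, since all sorted arrays below -0.1 precede all those above -0.1. With only the sorted arrays below it, a setting added after seeing the data, 669 genes passed, of which 293 were lower and the others, now the majority, higher, and the fibroblast, T and NK and B and plasma lists kept their calls, while the other 8 called lists lost theirs (adjusted p from 0.121 to 0.296).

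**Figure D1:**
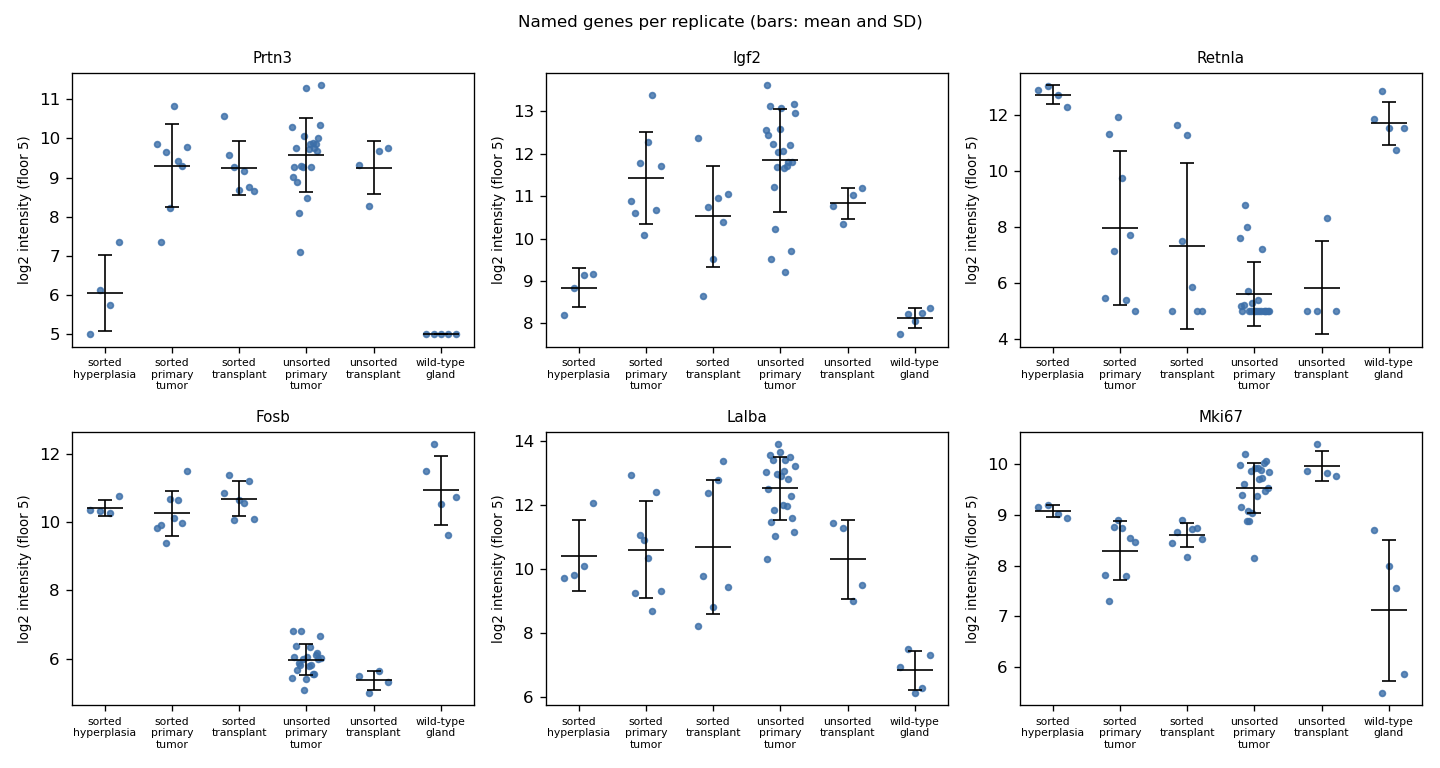
Log2 intensity of 6 named genes in each replicate of the 6 groups (vertical axis, floor at 5; horizontal axis, group). Each point is 1 replicate and bars give mean and SD. Prtn3 was at 9.30 in sorted tumors and at the floor of 5 in all wild-type glands, and Fosb was at 5.98 in unsorted primary tumors against 10.25 in sorted ones.

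Unsorted primary tumors were then set against wild-type glands, which stand apart from them in the sample order. Of 14 milk and alveolar genes 10 were higher in tumors, but the list was not called with an estimated correlation (camera adjusted p = 0.134). Lalba, the alpha-lactalbumin gene, rose by 5.84 ± 0.65 (12.52 ± 0.98, SD, n = 22, against 6.84 ± 0.61, n = 5, limma adjusted p = 6.33e-10), Csn1s2a by 5.76 ± 0.55 and Csn2 by 3.08 ± 0.36. Wap did not pass (1.33 ± 0.62, adjusted p = 0.0694), but did in 6 other settings (adjusted p from 0.0231 to 0.0472). Proliferation genes rose together, with Ube2c at 3.40 ± 0.32, Cdk1 at 3.06 ± 0.32, Birc5 at 3.03 ± 0.29 and Mki67 at 2.45 ± 0.30. Prtn3 and Pglyrp1, a peptidoglycan-binding protein gene, were at the floor in all glands and at least 23.7-fold and 27.4-fold higher in tumors. Col9a1 (4.35 ± 0.52), the myeloid gene S100a8 (4.33 ± 0.71), Cited4 (4.29 ± 0.46) and the arginase gene Arg1 (4.14 ± 0.54) rose as well. In the other direction lay Retnla (-6.22 ± 0.96), the endothelial selectin gene Selp (-6.08 ± 0.42), the cytokine gene Il6 (-6.03 ± 0.46), the matrix gene Dcn (-5.60 ± 0.88), Tnfaip6 (-5.33 ± 0.53), Fabp4 (-5.31 ± 0.77), Dpt (-5.12 ± 0.60) and Fosb (-4.94 ± 0.28). Il6 was above the floor in 1 of 23 tumor arrays, Selp in 7, Retnla in 11, Dpt in 14, Dcn in 21 and Fabp4 in 22, so the floor limits these differences. S100a8 was above it in 2 of 5 gland arrays, Arg1 and Birc5 in 3, and Csn1s2a and Ube2c in 4. Of 15150 genes 7722 passed, 4460 higher and 3262 lower in tumors.

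All 8 AP-1 subunit genes fell (8 adjusted over the list alone, median -2.55, camera adjusted p = 4.9e-11), with Fosl1 at -4.07 ± 0.35, Atf3 at -3.25 ± 0.39, Fos at -3.23 ± 0.40, Jun at -1.77 ± 0.24 and Junb at -1.65 ± 0.25. Of 20 immediate early genes 18 fell (18 adjusted over the list alone, median -2.27), among them Dusp1 (-3.96 ± 0.39) and Egr2 (-3.67 ± 0.44). Egr3 (-3.63 ± 0.46) had another probe set called in the opposite direction. All 13 endothelial genes fell (13 adjusted over the list alone, median -2.57), with Tek at -3.12 ± 0.22, Vwf at -3.07 ± 0.37 and Cdh5 at -2.91 ± 0.39. Hormone-sensing genes fell in 6 of 9 (6 adjusted over the list alone, median -1.11), with Pgr, the progesterone receptor gene, at -2.44 ± 0.29 and Esr1 at -0.93 ± 0.30, and Cited1 at least 7.26-fold lower. Without gland replicate 2 Esr1 lost its call (-0.67, adjusted p = 0.0811). Of 23 tumor arrays 7 were above the floor for Fosl1, 9 for Tek, 18 for Egr3, 19 for Vwf, 21 for Egr2 and 22 for Pgr. These 4 lists were also called with an estimated correlation, at adjusted p from 0.00158 to 0.00995.

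Camera called 6 other lists with the preset correlation and not with the estimated one. Fry, which tests whether a list's genes move on balance 1 way and not against other genes, also called these 6, at adjusted p from 4.65e-10 (mesenchymal transition) to 0.0021 (B and plasma). Of 27 cell cycle genes 24 rose (24 adjusted over the list alone, median 1.64, adjusted p = 0.114 with an estimated correlation). Of 14 milk and alveolar genes 10 rose (11 adjusted over the list alone, median 1.59, adjusted p = 0.134 with an estimated correlation). Of 17 fibroblast genes 16 fell (17 adjusted over the list alone, median -2.45, adjusted p = 0.211 with an estimated correlation). Of 13 basal and myoepithelial genes 6 fell, led by the smooth muscle genes Myh11 (-4.54 ± 0.44) and Cnn1 (-3.22 ± 0.42), and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.451 with an estimated correlation). Krt5 (-0.67 ± 0.87) and Krt14 (-0.92 ± 0.54) did not pass, though Krt14 did with quantile normalization (-1.26, adjusted p = 0.0465). Of 11 B and plasma genes 5 fell (6 adjusted over the list alone, adjusted p = 0.531 with an estimated correlation), with Jchain at -4.28 ± 0.66. Without gland replicate 4 the B and plasma call was lost (median -0.15, adjusted p = 0.252), as it was with the floor at 100 (0.0547). Of 8 mesenchymal transition genes 5 fell (5 adjusted over the list alone, adjusted p = 0.051 with an estimated correlation), with Zeb1 at -1.87 ± 0.30, and the call was lost with the floor at 100 (adjusted p = 0.216). Cnn1 was above the floor in 6 of 23 tumor arrays, Myh11 in 9 and Jchain in 11. Luminal keratin genes Krt8 (-0.04 ± 0.25) and Krt18 (0.13 ± 0.28) did not pass.

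Etv6 did not differ past the threshold (0.08 ± 0.25, adjusted p = 0.807). Ntrk3 rose by 1.20 ± 0.24, but it was at the floor in 4 of 5 glands, 2 of its other probe sets were called in the opposite direction, and it did not pass with the floor at 100 (adjusted p = 1) or with the mean of its probe sets (-0.0035, 0.976). Whether any of these probe sets reads the fused transcript is not given in the sources used here, so they check nothing about the allele. The 3' over 5' ratio of the Actb control probe sets, a measure of RNA integrity, was 0.56 ± 0.26 (n = 22) in tumors and 0.95 ± 0.75 (n = 5) in glands (exact permutation p = 0.054, 0.135 adjusted over 15 tests), and gland replicate 4 stood at 2.18.

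Progression and tumor against gland, which share no array, overlapped. Of 195 genes higher in sorted tumor cells than in hyperplasia, 108 were also higher in tumors than in glands (57.4 expected if independent, Fisher's exact p = 3.76e-14) and 29 were lower (42.0 expected). Of 378 genes lower in sorted tumor cells, 216 were also lower in tumors than in glands (81.4 expected, Fisher's exact p = 1.33e-52) and 17 were higher (111.3 expected). Genes are not independent, and both comparisons use 1 estimate of the spread per gene. The overlap of higher genes was lost in 5 settings added after seeing the data. With the spike-in signal as a covariate 12 of 36 higher genes were shared (10.9 expected, Fisher's exact p = 0.717) and 95 of 122 lower genes (27.1 expected, p = 3.66e-39). Without hyperplasia replicates 1 and 2 together 4 of 7 higher genes were shared (2.08 expected, exact p = 0.207) and 67 of 77 lower genes (16.8 expected, exact p = 3.05e-34). For higher genes Fisher's exact p was 0.254 with the macrophage list mean as a covariate, 0.0507 with the Gapdh ratio set of the sorted arrays as a term and 0.278 with only the sorted arrays of low Gapdh ratio. In these 3 settings the overlap of lower genes had p from 1.09e-63 to 1.87e-21.

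The sort itself was examined by setting sorted against unsorted primary tumors, which came from different mice and stand apart in the sample order. Stress and early response genes were higher in sorted cells: the chemokine gene Cxcl2 rose by 5.60 ± 0.40 (11.13 ± 0.85, SD, n = 8, against 5.44 ± 1.09, n = 22, limma adjusted p = 5.51e-15), the phosphatase gene Dusp1 by 4.56 ± 0.34, the heat shock gene Hspa1a by 4.37 ± 0.25, Fosb by 4.29 ± 0.24 and the nuclear receptor gene Nr4a3 by 3.87 ± 0.27. The beta-globin gene Hbb-b2 had the largest fall, -2.92 ± 0.46, followed by Pglyrp1 (-2.67 ± 0.63), Lalba (-2.34 ± 0.57), Tfcp2l1 (-2.10 ± 0.57) and Pdia3 (-2.06 ± 0.31). Nr4a3 was above the floor in 2 of 23 unsorted tumor arrays and Cxcl2 in 5, and in sorted tumors Hbb-b2 was above it in 2 of 8 arrays and Pglyrp1 and Tfcp2l1 in 7. In all 3832 genes passed, 1458 higher and 2374 lower in sorted cells.

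All 8 AP-1 genes rose with the sort (8 adjusted over the list alone, median 2.63), as did 17 of 20 immediate early genes (18 adjusted over the list alone, median 2.34), and both lists were also called with an estimated correlation (adjusted p = 1.25e-10 and 7.17e-10). Of 12 RAS-MAPK feedback genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.0665 with an estimated correlation), with Hbegf, above the floor in 22 of 23 unsorted tumor arrays, at 3.80 ± 0.39, Dusp5 at 3.69 ± 0.34 and Spry2 at 1.52 ± 0.20. Of 27 cell cycle genes 17 fell (20 adjusted over the list alone, median -0.73, adjusted p = 0.27 with an estimated correlation), including Ube2c (-1.42 ± 0.28), Aurka (-1.41 ± 0.20) and Top2a (-1.32 ± 0.30). Macrophage genes rose in 6 of 20 (6 adjusted over the list alone, median 0.93, adjusted p = 0.581 with an estimated correlation), with Mrc1 at 2.28 ± 0.53 and Csf1r at 1.96 ± 0.50. MHC class II genes rose in 3 of 6 (4 adjusted over the list alone, adjusted p = 0.581 with an estimated correlation). The fibroblast list was called higher with 2 of 17 members (2 adjusted over the list alone, adjusted p = 0.643 with an estimated correlation). With the macrophage list mean as a covariate, added after seeing the data, 2522 genes passed, and the MHC class II and fibroblast calls were lost (adjusted p = 0.26 and 0.804). This covariate removes the macrophage list's own shift by construction. Actb and Gapdh 3' over 5' ratios were lower in sorted tumors by differences of -0.27 and -0.21 (exact permutation p = 0.00895 and 0.0089, both 0.0672 adjusted over 15 tests). Single tumors were permuted here, though several came from the same mouse.

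Transplanted tumors were compared with primary tumors separately for sorted and unsorted samples. In sorted cells no gene passed in limma, and 606 had an unadjusted p under 0.05 against 757.5 expected by chance. The macrophage list was called lower in sorted transplants (median -0.76, camera adjusted p = 4.99e-11) and the interferon response list higher (median 0.79, adjusted p = 1.32e-05), with no member of either past the threshold over all genes or adjusted over the list alone. With an estimated correlation their adjusted p were 0.482 and 0.638. With mouse of origin as a fixed block, added after seeing the data and resting on the 2 mice with both kinds of tumor, 1 gene passed and the interferon call was lost (median -0.051, adjusted p = 0.622). With array weights 4 genes passed, and 2 passed with quantile normalization, without the transplants of mouse D279, or with only the sorted arrays of low Gapdh ratio.

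In unsorted tissue, transplants had higher Slc6a15, an amino acid transporter gene (8.53 ± 0.43, SD, n = 4, against 5.46 ± 0.70, n = 22; difference 3.10 ± 0.44, limma adjusted p = 2.05e-05). Sema3b rose by 3.05 ± 0.67, Arsi by 2.68 ± 0.32, Reep1 by 2.45 ± 0.22 and Krtap8-1, above the floor in 2 of 4 transplant arrays, by 2.11 ± 0.40. Of 23 primary tumor arrays 2 were above the floor for Krtap8-1, 6 for Reep1, 11 for Slc6a15 and 22 for Sema3b. The chloride channel accessory genes Clca3a2 and Clca3a1 had differences of -3.74 ± 0.63 and -3.44 ± 0.57, Slc39a8 of -3.20 ± 0.83 and Trim30a of -2.79 ± 0.73. Both Clca genes were above the floor in 3 of 4 transplant arrays. Klhl13 was at the floor in all 4 transplant arrays and at least 7.25-fold lower. In all 143 genes passed, 114 higher and 29 lower. The BioB and BioC spike-in signal was lower in transplants by a difference of -0.61 and the Actb 3' over 5' ratio by -0.28 (exact permutation p = 0.0148 and 0.0373, 0.0739 and 0.127 adjusted over 15 tests). These tests permuted single replicates, though the 4 transplants came from 2 mice. Spike-in signal was 7.98 to 8.49 in transplants. In primary tumors it was at most 8.47 for mice CR115, B459 and C117 and at least 8.77 for the others. In the sample order transplants stand among or directly after the tumors of these named mice and before the others. A difference between these sets of arrays was not tested, and this comparison cannot tell it apart from transplantation. The interferon list was called lower with no member of 11 past the threshold over all genes and 10 adjusted over the list alone (median -1.51, adjusted p = 1.28e-08, and 0.166 with an estimated correlation). The milk list (median -0.65, 3 of 14 lower adjusted over the list alone) and the MHC class II list (median -1.12, none of 6 adjusted over the list alone) were called lower, and had adjusted p = 0.166 and 0.483 with an estimated correlation. The cell cycle list (median 0.35, none of 27 adjusted over the list alone) and the RAS-MAPK feedback list (median 0.58, 2 of 12 adjusted over the list alone, Etv4 1.03 ± 0.21 over all genes) were called higher, and had adjusted p = 0.687 and 0.166 with an estimated correlation. Macrophage (median -0.41, none of 20 lower and 1 adjusted over the list alone) and hormone-sensing (median -0.09, 1 of 9 lower and 2 adjusted over the list alone, with Esr1 at least 2.71-fold lower) lists were called lower at adjusted p = 0.0383 and 0.0454, and had 0.799 and 0.166 with an estimated correlation. The 4 arrays came from 2 mice of origin: 75 or 66 genes passed without transplant replicate 1 or 2, 41 with arrays averaged per mouse and 822 with no mouse block. Trim30a and Esr1 lost their calls without any 1 transplant replicate (adjusted p from 0.051 to 0.151 and from 0.0658 to 0.09), Slc39a8 without replicate 1, 2 or 4 (0.0931, 0.0925 and 0.195), the hormone-sensing list without 1, 2 or 3 (0.0523, 0.0727 and 0.0627) and the macrophage list without 4 (0.145). Averaged per mouse, Esr1, Etv4, Klhl13, Slc39a8 and Trim30a lost their calls (0.288, 0.249, 0.266, 0.196 and 0.175). With mouse of origin as a fixed block, which rests on mouse CR115 alone, 737 genes passed, 541 higher and 196 lower. All 7 called lists then lost their calls (adjusted p from 0.0774 to 0.935), as did Esr1, Krtap8-1, Sema3b, Slc39a8 and Trim30a (0.141 to 1). The 2 arrays of the CR115 primary tumor had 42.9% and 41.4% of probe sets below the floor, against 38.3% and 39.3% in its transplants. A difference between arrays cannot be told apart from transplantation in this mouse.

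The difference between the sorted and unsorted transplant effects was tested directly, and 13 genes passed, 2 higher and 11 lower in sorted minus unsorted. Clca3a2 (3.88 ± 0.83) and Clca3a1 (3.48 ± 0.75) were the 2 higher genes, and Slc6a15 (-3.33 ± 0.58), Arsi (-2.99 ± 0.42), Reep1 (-2.53 ± 0.30) and Lmo4 (-1.67 ± 0.37) were among the lower ones. In sorted samples Reep1 was above the floor in 2 of 7 transplant and 1 of 8 primary arrays, and Slc6a15 in 3 of each. The interferon list differed by a median of 2.30 (camera adjusted p = 1.75e-13, 10 of 11 members adjusted over the list alone, adjusted p = 0.135 with an estimated correlation). The milk list differed by 1.06 (2 of 14 adjusted over the list alone) and the RAS-MAPK feedback list by -0.35 (2 of 12 adjusted over the list alone), with adjusted p = 0.339 and 0.723 with an estimated correlation. No gene was called in the same direction in both transplant comparisons, since none was called in the sorted one. Without unsorted transplant replicate 1, 3 or 4 the count was 7, 63 or 22, and with arrays averaged per mouse it was 5. Lmo4 lost its call without replicate 1 or 2 (adjusted p = 0.135 and 0.0581), Clca3a1 and Clca3a2 without replicate 4 (both 0.116) and the RAS-MAPK list without 1 or 2 (0.0947 and 0.0664). Averaged per mouse, Clca3a1, Clca3a2 and Lmo4 lost theirs (each 0.0728). With mouse of origin as a fixed block 24 genes passed, 12 in each direction, and these 6 genes and the 3 lists lost their calls (adjusted p from 0.0509 to 0.618). With no filter on dim probe sets 6 passed, and Clca3a1, Clca3a2 and Lmo4 lost theirs (0.0552, 0.0552 and 0.0582).

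**Figure D2:**
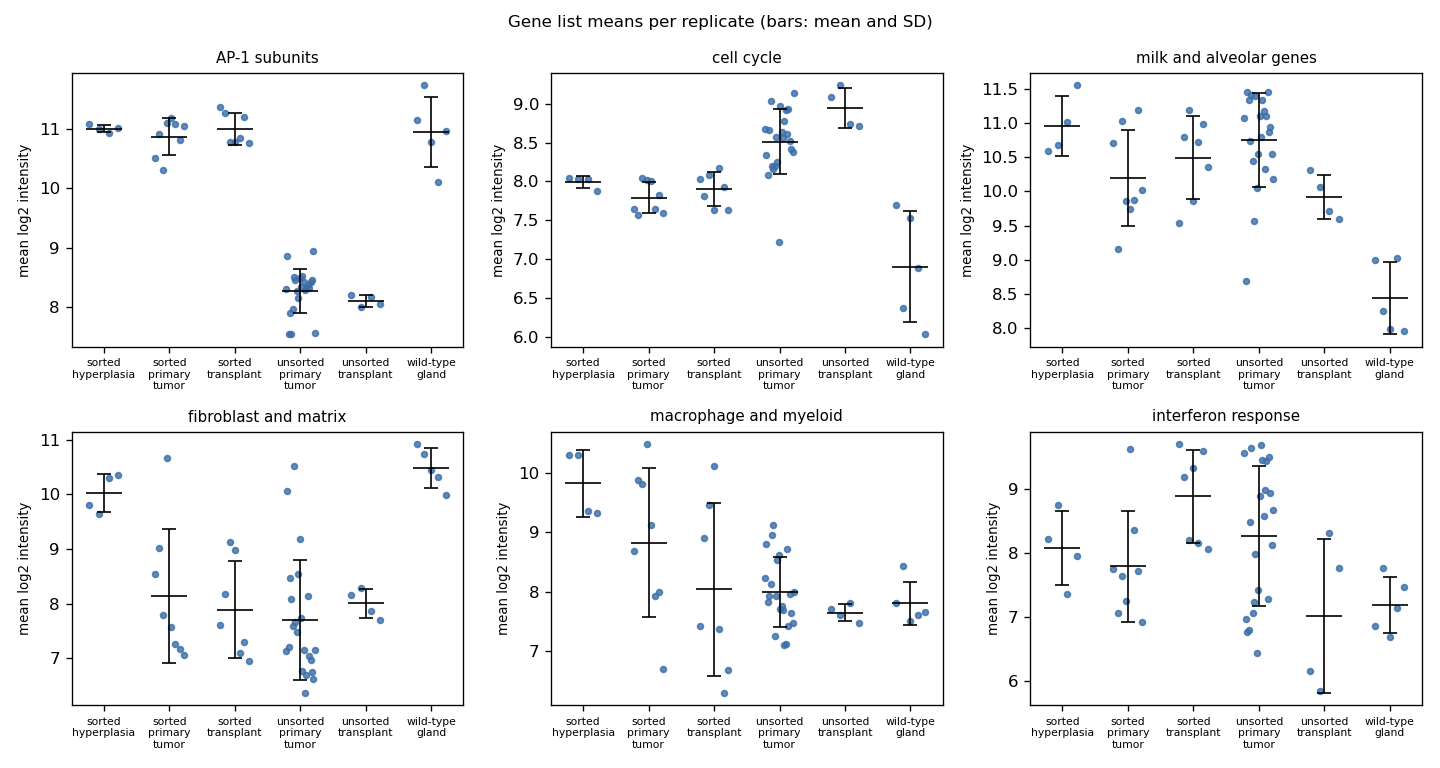
Mean log2 intensity of the genes of 6 lists in each replicate of the 6 groups (vertical axis, mean log2 intensity; horizontal axis, group). Each point is 1 replicate and bars give mean and SD. AP-1 means were 8.27 in unsorted primary tumors and 8.11 in unsorted transplants, against 10.86 in sorted primary tumors, 10.99 in sorted transplants and 10.94 in wild-type glands.

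Tumors of the same mouse were more alike than tumors of different mice. Among 22 unsorted primary tumors of 14 mice, 11 pairs from the same mouse had a mean gene-centred correlation of 0.213 ± 0.213 (SD over pairs) and 220 pairs from different mice had -0.0553 ± 0.185. The difference of 0.268 had a one-sided permutation p of 0.00018 (100000 resamples). Tumors of the same mouse also stand next to each other in the sample order. Spike-in signal was at most 8.47 in the tumors of mice CR115, B459 and C117 and at least 8.77 in the others. Mouse labels were shuffled over all tumors, so a likeness of arrays handled together was not tested and cannot be told apart.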

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

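Apart from the counts over splits of single arrays, the tests of explanations below, including the splits that kept mice together, were chosen only after the result was seen.

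The early response genes set unsorted tumors apart from every other group, wild-type glands included, although the labels call the glands unsorted too. In the sample order all unsorted tumors, transplants included, precede all sorted samples and glands. AP-1 list means reached at most 8.94 in unsorted primary tumors and at least 10.10 in glands. A difference in processing between these sets of arrays was not tested. It cannot be told apart from the sort or from tumor against gland. RNA degradation is argued against as the whole cause, since with the Actb 3' over 5' ratio as a covariate the immediate early list kept a median difference of -2.49 between tumors and glands. Stress during tissue dissociation stays open: of genes at least 4-fold higher in sorted tumors than in a part of the unsorted tumors, without the AP-1 and immediate early lists, 90.6% (85.1 to 95.3 over 100 halvings by mouse) were at least 2-fold higher in glands than in the remaining unsorted tumors, but both steps share a low side and the share decides nothing. How the glands were handled is not given in the sources used here. A loss of AP-1 expression between hyperplasia and tumor was not seen in sorted cells (list median -0.21, members from -0.63 to 0.80, against -2.55 between tumor and gland), and stays open because the list's median was 2.63 higher in sorted than in unsorted tumors and, with no unsorted hyperplasia, such a rise in both sorted groups would hide it.

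Stromal and immune lists were lower on average in sorted tumor cells than in sorted hyperplastic cells, though none of these calls held with an estimated correlation (camera adjusted p from 0.0587 to 0.558). Lower purity of the sorted hyperplastic cells may account for it and stays open. No pair of the 5 lists was shown to differ in its shift (smallest adjusted exact permutation p 0.384 over 10 pairs). With 4 against 8 arrays this does not show a common shift. The test also permuted single arrays, though 3 of the 8 tumor arrays came from 1 mouse. The luminal list was not called higher, but the hyperplasia arrays were not alike. Luminal means were 9.709 and 10.002 in replicates 1 and 2, against 10.865 and 10.831 in 3 and 4. Endothelial means were 6.25 and 5.87, against 7.23 and 7.25, and fibroblast means were also lower in 1 and 2. Tumor arrays varied too and overlapped the hyperplasia arrays in each of the 5 lists. Sorted tumor replicate 4 had fibroblast and macrophage means of 10.66 and 10.49, above every hyperplasia array (highest 10.36 and 10.31). The sorted tumor group means were 8.14 and 8.82. Low RNA input of hyperplasia replicates 1 and 2 stays open: it was not measured, and bright spike-ins are its only sign. Without both arrays 2 of the 5 lists, fibroblast and endothelial, were still called lower. These arrays also had the highest macrophage list means among hyperplasia samples (10.31 and 10.30, against 9.36 and 9.32). Their B and plasma and T and NK means were the highest too. Leaving them out therefore cannot separate low input from cell content. A biological difference in the cells around hyperplasia and tumor was not tested.

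The interferon list was lower in unsorted transplants than in unsorted primary tumors, a call lost with an estimated correlation (camera adjusted p = 0.166). Whether a single mouse of origin accounts for it stays open: transplants of mouse CR90 lay 2.07 SD below the primary tumor mean of 8.27 (transplant mean 6.01), while those of mouse CR115 lay at -0.213 SD (8.04) but differed by -1.52 from the primary tumor of their own mouse (9.56). The arrays of the CR115 primary tumor also had more probe sets below the floor than those of its transplants. All unsorted transplants share the low spike-in signal of the first arrays in the sample order, while most primary tumors do not. A difference between these sets of arrays was not tested for this list. Variation between mice of origin stays open, with an exact permutation p of 0.133 over the 105 arrangements of 2 transplant mice among 13 other mice with primary tumors, although no primary tumor lay as low as the CR90 transplant mean (lowest 6.45). The lymphocyte-deficient host could not be excluded or shown, since the list's median was 0.79 in the opposite direction in sorted transplants, a call lost with an estimated correlation (adjusted p = 0.638).

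For the counts of calls, 100 splits of the same arrays into groups of the same sizes were drawn, the real one included. These break up arrays of the same mouse, so splits with the same numbers of arrays and mice per group that kept each mouse's arrays of a group together were counted too, 21 for unsorted transplants, where no more exist, and 100 otherwise. For tumor against gland the real split, with 7722 genes, was the 1 of 100 as large in either set. The highest other called 694, and 5868 with mice kept together. For the sort the real split, with 3832, was also the 1 of 100 as large in either set, and the highest others called 157 and 709. Chance is unlikely to give either count, but 100 splits cannot exclude it. Nor do the splits separate these groups from the sample order, in which they stand apart. For progression 3 of 100 splits called at least the real 573 genes and the highest other called 857, but with mice kept together 8 of 100 did and the highest other called 1517, so chance was not excluded. For unsorted transplants 1 split, the real one with 143, was as large and the highest other called 44, but with mice kept together 2 of 21 were and the other called 243, so chance was not excluded. For the difference of transplant effects 4 of 100 splits called at least the real 13 genes and the highest other called 55, but with mice kept together 13 of 100 did and the highest other called 89, so chance was not excluded. For sorted transplants the real count was 0, which all 100 splits of either set reach by definition, so they decide nothing; the highest others called 846 and 605. Single splits with far more genes than the real one may reflect a structure of the samples, but what they had in common was not tested.

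By the test of the difference itself, the transplant effect differed between sorted and unsorted samples for 13 genes, a count of 5 with arrays averaged per mouse, and chance was not excluded for it as given above. The differences, sorted minus unsorted, were 3.88 for Clca3a2, 3.48 for Clca3a1, -3.33 for Slc6a15, -2.99 for Arsi, -2.53 for Reep1 and -1.67 for Lmo4. Outside the naming rule, and chosen after their values were seen, they were -2.33 for Prmt1, -1.65 for Nme4, -1.53 for Naa30, -1.42 for Lrrc1, -1.32 for Cnih2, -1.09 for Magef1 and -0.40 for Hdac8. Among lists the median difference was 2.30 for interferon response, 1.06 for milk and -0.35 for RAS-MAPK feedback genes, none called with an estimated correlation (adjusted p = 0.135, 0.339 and 0.723).

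In 30 of 377 groups of 4 to 10 samples, 1 sample lay apart from the others by a gap over the range above Dixon's critical value. For independent normal values chance gives about 1 in 20 groups, or 18.9. Here some groups lie at the floor, where a single sample above it gives a gap of 1, and the groups share arrays. Setting these counts side by side therefore tests no excess. Among sorted primary tumors replicate 4 was highest for Igkv6-14 (gap over range 1, the other 7 at the floor), Iglv1 (0.71), Ms4a1 (0.734), Pdgfra (0.722), Tek (0.708), Arsi (0.809) and Reep1 (1, the other 7 at the floor). Replicate 5 was highest for Igk (1) and Cxcl10 (0.600), replicate 7 was highest for Myh11 (0.625), and replicate 2 was lowest for Kit (0.562). Among sorted hyperplasia samples replicate 3 was highest for Fosl1 (0.929) and lowest for Igkv8-30 (0.838), and lowest for a list mean were replicate 2 for hormone-sensing genes (0.923), replicate 4 for cell cycle (0.878) and replicate 1 for erythroid genes (0.843). Among wild-type glands replicate 4 was highest for Glycam1 (0.875), Hmga2 (0.75) and the B and plasma list (0.866) and lowest for Cited1 (0.767). Gland replicate 1 was highest for Etv6 (0.756) and Mb (1, at 5.09 with the others at the floor), replicate 2 was highest for Tnfaip6 (0.853) and Ntrk3 (1, at 5.00 with the others at the floor), replicate 3 was lowest for Mmp3 (0.78) and Zeb1 (0.96), and replicate 5 was highest for S100a8 (0.821). Among unsorted transplants replicate 3 was highest for the adipocyte list (0.838) and replicate 2 for the mesenchymal list (0.88), and among sorted transplants replicate 4 was highest for the T and NK list (0.819).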

How the results depend on the processing

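The spike-in, macrophage, Gapdh and fixed mouse block settings were chosen after seeing the data; all others were planned. The cause of a changed count was not tested, except where fewer arrays or more probe sets enter by construction. Of 4691 alternative values of named genes 4311 kept direction and side of the threshold, 369 lost and 9 gained a call and 2 reversed, and of 3366 for lists 3135 kept both, 161 lost and 68 gained a call and 2 reversed. Of 179 named calls 99 held under every alternative run. Signal near the floor limits dim genes: tumor against gland, gene Gzmb moved to 0.0133 with the floor at 100, and gene Ntrk3 to -0.0035 with the mean of its probe sets. By replicate number no paired analysis was possible because these were given in accession order, but 2 mice among sorted and 1 among unsorted samples gave both primary and transplanted tumors. A fit paired by mouse, as a fixed block with only the groups compared, called 1 gene for sorted and 737 for unsorted transplants and 24 for their difference. In sorted transplants it turned the interferon list to -0.051, not called, and the basal list to -0.33, called lower.

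Progression calls numbered 1032 with every probe set, 887 with no mouse block, 356 with array weights, 158 with the spike-in covariate, 84 without the 2 hyperplasia arrays of highest spike-in signal, 13 with only its groups in the fit, 214 at adjusted p under 0.01, 297 at 2-fold or more and 157 to 946 leaving out 1 hyperplasia replicate. Tumor against gland gave 16245 with every probe set and 2761 at 2-fold or more. The sort gave 7835 with every probe set, 2522 with the macrophage covariate, 2151 at adjusted p under 0.01 and 620 at 2-fold or more. Sorted transplants gave 2 with quantile normalization, 4 with array weights, 2 without mouse D279 and 2 with sorted arrays of low Gapdh ratio. Unsorted transplants gave 245 with median centring, 226 with the floor at 100, 317 with every probe set, 822 with no mouse block, 41 with arrays averaged per mouse, 318 with array weights, 234 with only its groups, 53 at adjusted p under 0.01, 67 at 2-fold or more and 66 to 162 leaving out 1 replicate. The difference of transplant effects gave 21 with quantile normalization, 37 with median centring, 7 and 40 with floors at 16 and 100, 6 with no filter on dim probe sets, 26 with the mean of probe sets, 40 with every probe set, 2.1e+02 with no mouse block (68 higher, 138 lower), 5 with arrays averaged per mouse, 21 with array weights, 22 with the spike-in covariate, 8 with only its groups, 5 at adjusted p under 0.01 and 7 to 63 leaving out 1 replicate. The overlap of progression and tumor against gland was 193 with the floor at 100, 538 with every probe set, 500 with no mouse block and 107 with the spike-in covariate. Of 40 list calls 6 held with an estimated correlation, and fry called 20 of the 40 and 6 other lists.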

Other observations

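The tests of the similarity of tumors were planned, while the Xist values and the array pairs were looked at only after the data were seen.

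Between unsorted primary tumors and glands, further lists held members that moved without a camera call of the list. Fry, which does not compare a list with other genes, called the luminal (adjusted p = 0.00305), erythroid (0.0208) and interferon (0.0343) lists higher and the RAS-MAPK list lower (0.0134). Of 11 luminal genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.122), among them the mucin gene Muc1 (3.22 ± 0.42) and the tight junction genes Cldn7 (1.66 ± 0.33) and Cldn3 (1.64 ± 0.28). Of 9 luminal progenitor genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with Sox10 at 1.68 ± 0.27, Ehf at 1.55 ± 0.46 and Cd14 at -1.49 ± 0.37. Of 11 interferon genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.194). Bst2, at the floor in all glands, was at least 5.17-fold higher, Oas1a rose by 2.96 ± 0.46 and the chemokine gene Cxcl10, above the floor in 22 of 23 tumor arrays, had a difference of -2.25 ± 0.53. Of 12 RAS-MAPK feedback genes Etv5 rose (2.00 ± 0.36) and 3 fell, including Dusp5 (-3.36 ± 0.39) and Hbegf (-3.19 ± 0.45, 22 of 23 tumor arrays above the floor), with 1 and 3 adjusted over the list alone. Of 20 macrophage genes 3 rose and 4 fell (2 and 3 adjusted over the list alone), with S100a9 at 3.03 ± 0.73 and Mrc1 at -2.39 ± 0.61, and the list's median of 0.19 and mean of 0.15 lay above 0 while its test pointed down (adjusted p = 0.801).

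Of 14 hypoxia and glycolysis genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Egln3 at 2.62 ± 0.52 and Pgk1 at 1.31 ± 0.22. Adipocyte genes rose in 2 and fell in 4 of 10 (2 and 4 adjusted over the list alone), with Lpl at -2.13 ± 0.51. T and NK genes rose in 2 and fell in 4 of 13 (2 and 4 adjusted over the list alone), with Gzma at -1.21 ± 0.27. Among AP-1 associated invasion genes 2 rose and 1 fell of 8 (1 and 1 adjusted over the list alone), with Hmga2 at 2.32 ± 0.56 and Mmp3, above the floor in 12 of 23 tumor arrays, at -3.71 ± 0.53. Skeletal muscle genes rose in 2 and fell in 1 of 7 (2 and 1 adjusted over the list alone), with a median of 0.14 and a mean of -0.03, erythroid genes rose in 1 of 3 (1 adjusted over the list alone) and MHC class II genes rose in 1 and fell in 1 of 6 (1 and 0 adjusted over the list alone).

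The greater likeness of tumors of the same mouse held with the 1000 most variable genes (difference of mean r 0.272, one-sided permutation p = 0.0053), with the genes of the cell type lists left out (0.274, p = 0.0001) and without mouse C117 (0.356 over 5 pairs, p = 0.0002). Across genes, the 2 arrays of tumor CR115 correlated at 0.987, against a median of 0.924 for pairs of the other unsorted primary tumors. The unsorted transplant pairs of CR90 and CR115 correlated at 0.990 and 0.988, and transplants of CR90 with those of CR115 at 0.926 to 0.939. Among sorted samples, tumor F433T4 correlated with its transplant at 0.965, against a median of 0.899 and a highest value of 0.959 for primary and transplanted tumors of different mice. The arrays of F433T4 and its transplant stand next to each other in the sample order. The pairs of different mice include arrays from both sides of the Gapdh ratio cut. A likeness of arrays handled together cannot be told apart here.

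Xist, transcribed from the inactive X chromosome, was at 7.62 in sorted primary tumor replicate 7 and 7.13 in sorted transplant replicate 5, which is the transplant of that tumor. It was at 7.32 and 7.83 in unsorted transplant replicates 1 and 2, both from mouse CR90.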
